A study of Mus musculus with 8 samples.

How the data were processed

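RNA was taken from osteoblastic cells sorted by FACS from collagenase-digested mouse long bones, with an RNA integrity number above 6.5, and libraries were made with the SMART-Seq v4 low-input kit, per the labels' protocols. This kit amplifies cDNA copied from the poly(A) tail and does not mark strand, so antisense pairs and overlapping genes cannot be told apart. The 8 libraries were grouped by the disease state in the labels into 4 leukemic and 4 control libraries. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.8, DESeq2 and the build GRCm38.p6, without their settings.

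The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) with 2 decimals for 17068 genes, all typed as mRNA, per the file headers. The table also held the authors' group means and the authors' log2 ratio of leukemic over control, per the file headers, and the way that log2 ratio was made is not given in the sources used here. It lay within 0.01 of the log2 ratio of the group means in 1330 of 15705 genes with both means above 0, so it was used only for description. FPKM already divides by length and by library total, and RSEM shares multi-mapped fragments between genes, so near-identical genes can exchange signal. Steps of single reads were looked for in the ratios of low values between leukemic library 1 and each of the other 7 libraries. No ratio held more than 2.24% of the genes, in bins of 0.03 on the log2 scale, so the depth is unknown and no counting interval is given. An FPKM of 0 is described as listed at 0.

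Expression was analysed as log2(FPKM + 1), keeping genes with at least 1 FPKM in at least 4 libraries (11214 tested, 5854 not tested). Leukemic was compared with control by limma 3.58.1 (R 4.3.3) with moderated variances and a mean-variance trend, without covariates, with two-sided tests and Benjamini-Hochberg adjustment at 0.05. A count model was not used, since the values are not counts. Fold changes are leukemic minus control on the log2(FPKM + 1) scale. The 39 gene lists, the bone panel of 19 genes, the tests and the rule for named genes were fixed before the data were examined. The rule named the bone panel in full, and up to 10 genes per direction among those past the threshold with groups that did not overlap and a mean of at least 5 FPKM in the higher group, without predicted-gene symbols. As none passed, it named the 5 genes with the smallest p in each direction. It also named list members past the gene threshold, and markers of other cell types by abundance. Members that passed only when adjusted over the list alone, other list examples, Lyz2, Vpreb1, Igll1 and the predicted genes beside Ccl19 were chosen after their values were seen.

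Lists with at least 5 genes tested (35 lists) were tested with camera at a preset inter-gene correlation of 0.01, with camera at a correlation estimated per list, and with fry. With the estimated correlation and with fry, 0 of the 35 lists passed. Library measures were compared by exact permutation tests in scipy 1.17.1. Chromosomal positions came from a RefSeq gene table of the same build, matched by gene ID for 17022 of 17068 genes, and transcript lengths and sequences from GENCODE M21, with a length for 10980 (97.9%) of the genes tested. The limma step was tested before use on simulated data with 200 changed genes, and the camera step with the osteocyte list shifted. Simulated genes varied independently, so camera was not tested under correlation between genes.

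Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, 3 other scalings, robust and untrended variances, array weights, the replicate number as a block, leaving out each library, and 3 other list tests. After the data were seen, removal of the trend with transcript length in each library (lowess with a span of 0.3), its combinations with GC content and with the block, and leaving out leukemic libraries 1 and 2 were added, as was an estimated correlation in each alternative fit. The authors' group means were not used in any test. The result of 1 gene of the marker lists is not reported here.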

Results

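Gene expression was measured by RNA-seq in osteoblastic cells (OBCs), the cells that build bone matrix, sorted from the long bones of female C57BL/6J mice about 10 weeks old. There were 4 libraries of OBCs from mice bearing BCR-ABL+ B-cell acute lymphoblastic leukemia (B-ALL), a cancer of B-cell precursors that grows in the marrow, and 4 libraries of OBCs from healthy mice. The design asks how the transcriptome of bone-forming cells differs between leukemic and healthy animals, in a series about sclerostin, the secreted Wnt antagonist encoded by Sost, and bone loss in B-ALL. The deposited table gave FPKM values for 17068 genes, of which 11214 reached 1 FPKM in at least 4 of the 8 libraries and were tested. Read depth is unknown, because the table gives FPKM and no counts. The number of genes at 1 FPKM or more ran from 10911 to 11162 per library, and the summed FPKM from 456191 to 632055. The labels do not state that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

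The 8 libraries did not part by disease state. Pearson correlations of log2(FPKM + 1) ran from 0.89 to 0.964 among leukemic libraries, from 0.938 to 0.967 among control libraries and from 0.902 to 0.975 between the groups. The first principal component held 40.4% of the variance, and its gene loadings followed transcript length across genes (Spearman rho 0.43; genes are not independent replicates). Within each library, the deviation of genes from their mean over libraries had a Spearman rho with transcript length of -0.352, -0.342, -0.114 and 0.324 in leukemic libraries 1 to 4, and of 0.038, 0.143, 0.123 and 0.347 in control libraries 1 to 4. Leukemic libraries 1 and 2 were therefore richer in short transcripts than the other 6 libraries. The slope on length did not differ between the groups beyond the spread of libraries (exact permutation p = 0.2286, two-sided).

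With predicted-gene symbols left out, the genes with the smallest p-values among those higher in leukemic OBCs encoded chemokines, complement and phagocyte proteins. Ccl19, a chemokine that attracts lymphocytes and dendritic cells through Ccr7, had a mean of 131 ± 96.3 FPKM (SD, n = 4) in leukemic and 6.51 ± 3.20 FPKM (n = 4) in control libraries. Cxcl13, a B-cell attracting chemokine, stood at 14.7 ± 4.97 against 1.33 ± 0.933 FPKM, and C3, the central complement component, at 85.3 ± 25.1 against 20.3 ± 7.96 FPKM. Slamf8, a receptor of myeloid cells, stood at 3.04 ± 1.56 against 0.0425 ± 0.0723 FPKM, and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, at 6.86 ± 1.95 against 1.40 ± 0.737 FPKM. In each of these 5 genes all 4 leukemic libraries lay above all 4 control libraries, but none passed the threshold of limma with Benjamini-Hochberg adjustment over all genes. On the log2(FPKM + 1) scale, which understates the change of low genes, the fold changes were 3.88 (SE 0.58) for Ccl19, 2.79 (SE 0.37) for Cxcl13, 2.04 (SE 0.32) for C3, 1.87 (SE 0.28) for Slamf8 and 1.74 (SE 0.30) for Cybb. The adjusted p was 0.144 for the first 4 of these and 0.27 for Cybb. Without leukemic library 4, Ccl19 passed (adjusted p = 0.0062), and with the length trend removed in each library Ccl19 (adjusted p = 0.000249) and C3 (adjusted p = 0.0448) passed. With array weights Slamf8 (adjusted p = 0.0157), Ccl19 (0.0157), C3 (0.026) and Cxcl13 (0.0423) passed. Ccl19 also passed with quantile normalization (adjusted p = 0.0288), as did Cxcl13 (0.0288), and with totals rescaled to TPM (0.0394).

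In GRCm38.p6, Ccl19 (gene ID 24047) spans chromosome 4, 42754525 to 42756365. Cxcl13 (55985) spans chromosome 5, 95956939 to 95961068. C3 (12266) spans chromosome 17, 57203967 to 57228136. Slamf8 (74748) spans chromosome 1, 172581377 to 172590873, and Cybb (13058) chromosome X, 9435252 to 9487766. The value of Ccl19 is uncertain, because reads could be split between it and near-identical copies. In 4 other genes of the transcript reference, at least 50% of the 31-base subsequences were also found in Ccl19 transcripts. Of these, Gm2564 (77.7%) and Gm12407 (80.6%) were in the table, and the other 2 were not analysed here. Summed over Ccl19, Gm2564 and Gm12407, the level was 199.99 ± 152.99 FPKM (SD, n = 4) in leukemic and 12.66 ± 6.55 FPKM (n = 4) in control libraries. Gm2457 was listed with the same values as Gm2564 in every library but was not in this sum. The predicted genes LOC100043921 and Gm13309 were also higher in all 4 leukemic libraries. Their limma p-values of 3.41e-05 and 6.84e-05 (adjusted p = 0.144 for both) were smaller than that of C3 (7.71e-05). Their sequences were not compared, they were not in the sum, and they were chosen after their values were seen.

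With predicted-gene symbols left out, the genes with the smallest p-values among those lower in leukemic OBCs showed smaller differences. Plod2, the lysyl hydroxylase that prepares collagen telopeptides for crosslinking, stood at 42.7 ± 4.75 FPKM (n = 4) in leukemic and 80.4 ± 11.6 FPKM (n = 4) in control libraries, a log2 fold change of -0.89 (SE 0.17, adjusted p = 0.314). Epb41l4b stood at 1.71 ± 0.212 against 5.23 ± 2.27 FPKM, and Ell2, a transcription elongation factor, at 5.45 ± 0.779 against 11.3 ± 2.41 FPKM. Slc30a9, a zinc transporter, stood at 3.66 ± 0.456 against 7.33 ± 0.862 FPKM, and Ndfip2, an adaptor of Nedd4-family ubiquitin ligases, at 8.06 ± 1.44 against 14.7 ± 0.679 FPKM. All 4 leukemic libraries lay below all 4 control libraries in these 5 genes, and the adjusted p of the last 4 ran from 0.376 to 0.402. Plod2 (26432) lies on chromosome 9, 92539636 to 92608428, and Epb41l4b (54357) on chromosome 4, 56991972 to 57143168. Ell2 (192657) lies on chromosome 13, 75707484 to 75772361. Slc30a9 (109108) lies on chromosome 5, 67306955 to 67356142, and Ndfip2 (76273) on chromosome 14, 105258591 to 105309298.

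Across all 11214 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.144. At an unadjusted p under 0.05 there were 279 higher and 463 lower genes. The balance of directions depended on the processing. Higher and lower genes numbered 633 and 405 with the replicate block, 372 and 418 with the length trend removed, and 171 and 725 with totals rescaled to TPM. Groups did not overlap in 107 genes with all leukemic libraries above and 325 with all below, together 3.85% of genes, where chance gives 2.86%. In simulated data with the same spread per gene, the test recovered 40.5% of 200 genes changed by a log2 fold of 1. It recovered 88% of those changed by 2 and 99.5% of those changed by 3. The simulated genes varied independently and without a length trend, so these shares need not hold for the real libraries. In the authors' deposited table the log2 column, whose method is not given in the sources used here, had the sign of the limma estimate in 94.0% of the genes tested, with 4.41 for Ccl19, 3.50 for Cxcl13 and 2.19 for C3.

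**Figure D1:**
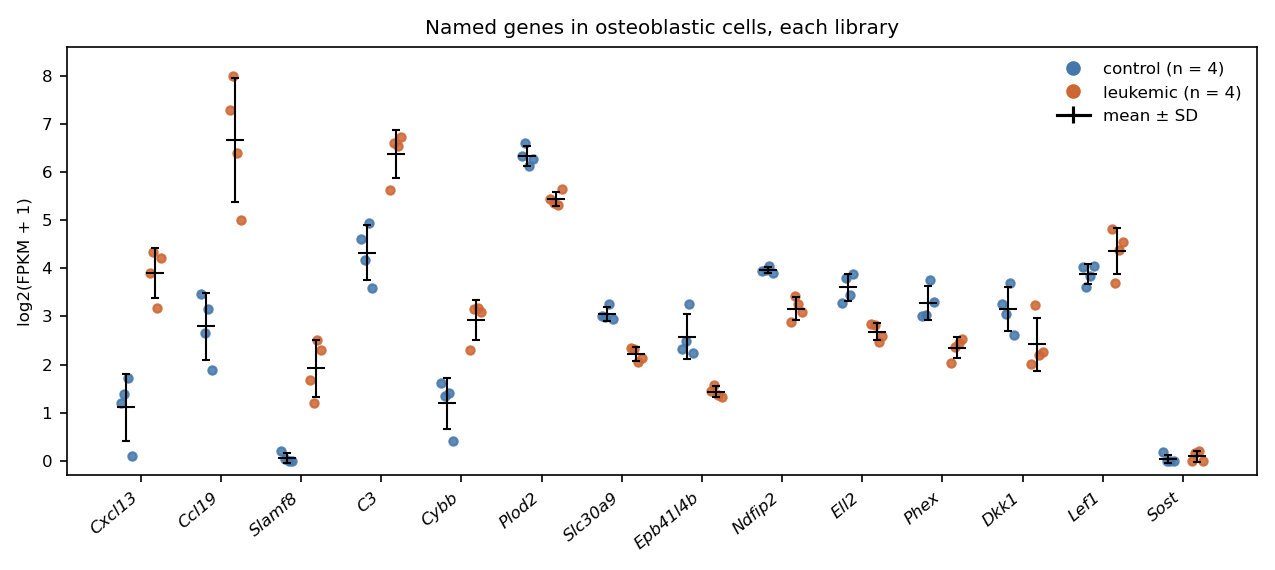
Expression of 14 named genes as log2(FPKM + 1) in each of 4 control (blue) and 4 leukemic (orange) libraries, with bars for the mean ± SD of the logs. Leukemic libraries sit above all controls for Cxcl13, Ccl19, Slamf8, C3 and Cybb and below all controls for Plod2, Slc30a9, Epb41l4b, Ndfip2, Ell2 and Phex, while Sost lies at the floor in both groups.

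In the bone panel, fixed before the data were examined, Phex stood apart and Sost was near the floor of the table. Sost (gene ID 74499, chromosome 11, 101962458 to 101967015), which encodes sclerostin and marks mature osteocytes, was listed at 0, 0.12, 0.16 and 0 FPKM in leukemic and at 0.13, 0, 0 and 0 FPKM in control libraries. It was too low to be tested, as were Fgf23 and Axin2. Phex (18675, chromosome X, 157162075 to 157415286), a peptidase needed for normal mineralization, stood at 4.14 ± 0.723 FPKM (n = 4) in leukemic and 8.90 ± 2.57 FPKM (n = 4) in control libraries. Its log2 fold change was -0.92 (SE 0.22), with all 4 leukemic libraries below the controls, and it was the only panel gene past the threshold when adjusted over the list alone (limma adjusted p = 0.0271, against 0.444 over all genes). Dkk1, a secreted Wnt antagonist, stood at 4.69 ± 2.49 against 8.23 ± 2.83 FPKM, and Mepe, an osteocyte matrix protein, at 13.1 ± 6.41 against 21.5 ± 10.2 FPKM. The collagen gene Col1a1 stood at 6275 ± 2972 against 7880 ± 1051 FPKM. Sp7, a transcription factor required for osteoblast formation, stood at 41.6 ± 9.92 against 55.5 ± 9.54 FPKM, and Lef1, a Wnt-responsive transcription factor, at 20.4 ± 6.44 against 13.8 ± 1.98 FPKM. Runx2 (log2 fold change -0.20), Alpl (-0.12), Ibsp (-0.10) and Spp1 (-0.03) differed by less than the spread between libraries. So did Dmp1 (-0.33), Tnfsf11 (-0.19), Tnfrsf11b (-0.05), Cxcl12 (-0.19) and Kitl (-0.08). Bglap, which encodes osteocalcin in a short transcript, had a log2 fold change of 0.20 that turned to -1.002 when the length trend was removed.

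The interferon and inflammatory lists passed in the higher direction in leukemic OBCs by camera with its preset correlation, a test of whether a list moves more than other genes. No member passed over all genes, and with an estimated correlation no list passed, in this fit or in any alternative fit run (lowest adjusted p 0.333). Of the 26 type I interferon response genes tested, 25 had a positive log2 fold change, with a mean of 0.70 (SE 0.289 between libraries; camera adjusted p = 1.78e-10; adjusted p = 0.48 with an estimated correlation). In this list 3 genes passed adjusted over the list alone: Zbp1, a sensor of Z-form nucleic acid (11.0 ± 4.07 against 2.92 ± 2.27 FPKM), Xaf1 (11.8 ± 6.49 against 3.46 ± 1.52 FPKM) and Isg15, a ubiquitin-like protein (11.2 ± 5.85 against 3.14 ± 1.70 FPKM). The inflammation and NF-kB list rose by a mean of 0.54 (SE 0.3) with 20 of 27 genes positive (camera adjusted p = 6.04e-05; adjusted p = 0.48 with an estimated correlation). Its 3 members that passed adjusted over the list alone were C3, the acute phase gene Saa3 (10.7 ± 9.55 against 0.565 ± 0.707 FPKM) and the interferon-induced chemokine Cxcl9 (21.7 ± 8.98 against 7.21 ± 3.89 FPKM), whereas Nfkb1 had a log2 fold change of -0.60. The interferon gamma and antigen presentation list rose by a mean of 0.37 (SE 0.334) with 24 of 29 genes positive (camera adjusted p = 0.000176; adjusted p = 0.501 with an estimated correlation) and 0 genes past the threshold adjusted over the list alone. Its mean was 0.21 without leukemic library 2 (adjusted p = 0.0362), 0.23 without control library 2 (adjusted p = 0.0238) and 0.60 without control library 3 (adjusted p = 1.74e-10). The senescence list, which shares Cxcl1, Ccl2 and Il6 with the inflammatory and cytokine lists, had a mean of 0.40 with 12 of 17 genes positive (camera adjusted p = 0.0285; adjusted p = 0.48 with an estimated correlation). This call was lost when the length trend was removed (mean 0.295, adjusted p = 0.067) and without leukemic library 2 (mean 0.25, adjusted p = 0.19). It was also lost with a filter of 5 FPKM (adjusted p = 0.0519), with array weights (adjusted p = 0.0571), by camera on ranks (adjusted p = 0.0589) and without leukemic libraries 1 and 2 (adjusted p = 0.149). Beside these lists, the pan-leukocyte markers had a mean log2 fold change of 0.10 over the 5 genes tested, and the B-lineage markers of 0.51 over 3, all 3 positive. Without the low-value filter, the B-lineage list passed camera with a mean of 0.27 over 22 genes (adjusted p = 0.00265; adjusted p = 0.583 with an estimated correlation). Of the macrophage and monocyte markers, Lyz2 was 39.9 FPKM higher in the leukemic mean, while Cd68 differed by -1.79, Cd14 by -0.30 and C1qa by -0.23 FPKM. Of the B-lineage genes, Vpreb1 was 1.92 and Igll1 1.42 FPKM higher.

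**Figure D2:**
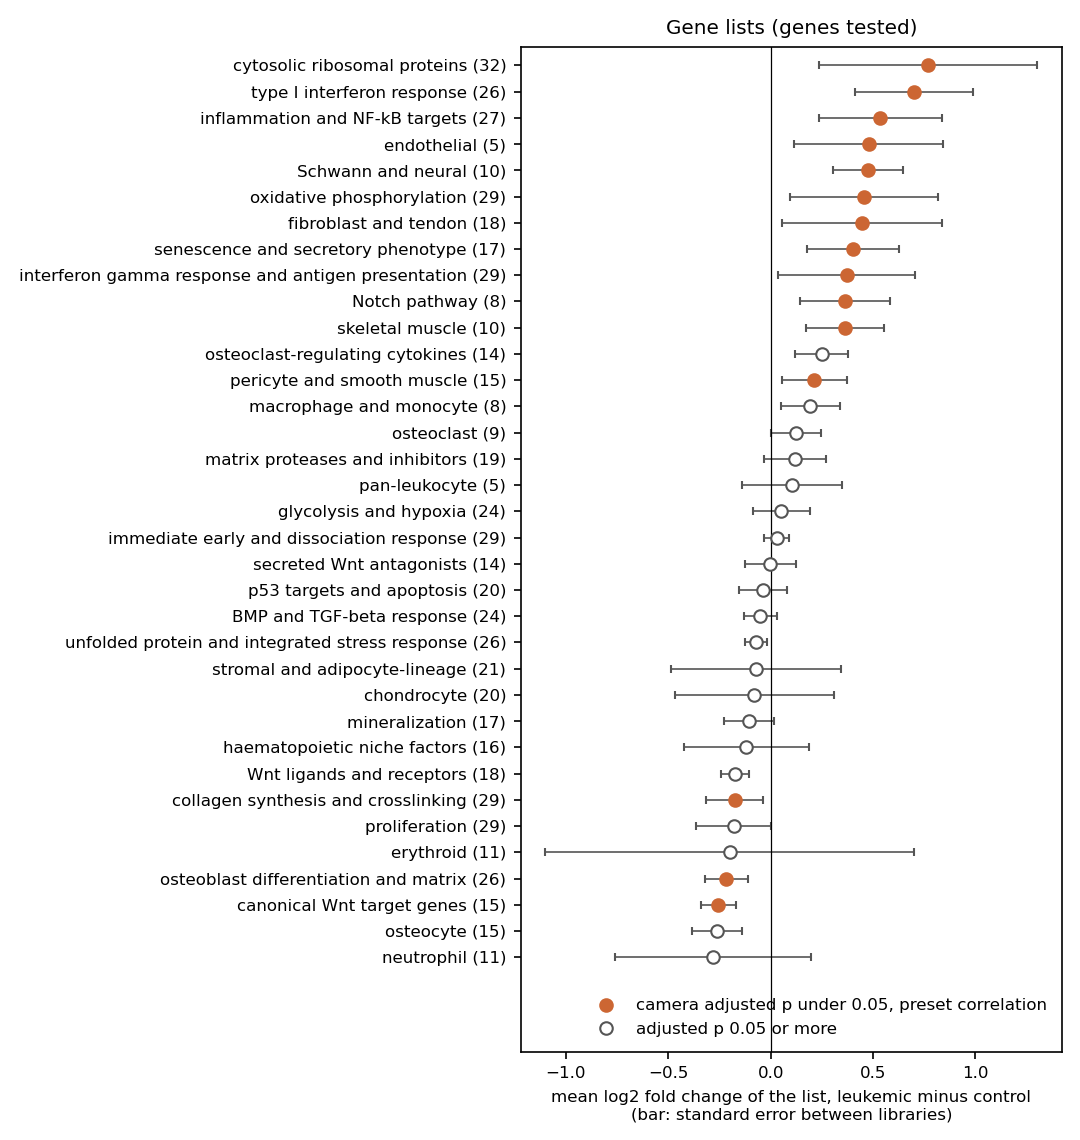
Mean log2 fold change (leukemic minus control) of each of 35 gene lists, with bars for the standard error between libraries and the number of genes tested in parentheses. Filled points mark the 15 lists past the camera threshold with the preset correlation, 12 higher and 3 lower, none of which passed with an estimated correlation.

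Bone matrix, collagen and Wnt target lists fell in leukemic OBCs by camera. Of 26 osteoblast genes, 20 had a negative log2 fold change, with a mean of -0.22 (SE 0.107; camera adjusted p = 0.0158; adjusted p = 0.48 with an estimated correlation). Examples were Dlx3, an osteogenic homeobox gene (4.90 ± 1.71 against 9.82 ± 1.70 FPKM), and Col1a2 (3895 ± 1154 against 5735 ± 301 FPKM), neither of which passed adjusted over the list alone. The collagen synthesis and crosslinking list had 19 of 29 genes negative and a mean of -0.17 (SE 0.14; camera adjusted p = 0.0158; adjusted p = 0.523 with an estimated correlation). Plod2 passed adjusted over the list alone, and Loxl2, a lysyl oxidase, stood at 8.57 ± 2.06 against 15.8 ± 3.28 FPKM without passing. The 15 canonical Wnt target genes had a mean of -0.25 (SE 0.087) with 11 negative (camera adjusted p = 0.0285; adjusted p = 0.48 with an estimated correlation). Ccn4 stood at 22.7 ± 5.47 against 37.5 ± 8.66 FPKM and Tcf7 at 1.97 ± 0.114 against 4.23 ± 2.31 FPKM, while Lef1 of the same list was higher, and none of the 15 passed adjusted over the list alone. The osteoblast call was lost without leukemic library 3 (adjusted p = 0.0768) or control library 3 (mean -0.13, adjusted p = 0.199). The collagen mean was -0.01 without leukemic libraries 1 and 2, and its call was lost without leukemic library 2 (mean -0.07, adjusted p = 0.264) or control library 2 (adjusted p = 0.0519). It was also lost by camera on ranks (adjusted p = 0.0588). Without leukemic library 4 the collagen mean was -0.28 (adjusted p = 0.00135). The Wnt target call was lost with the length trend removed (mean -0.20, adjusted p = 0.067), without the filter (adjusted p = 0.146), with a filter of 5 FPKM (adjusted p = 0.128), with array weights (adjusted p = 0.0571) and without leukemic libraries 1 and 2 (adjusted p = 0.149). It was also lost without leukemic library 1 or 4 or control library 2 or 3 (adjusted p = 0.058, 0.0614, 0.0519 and 0.0829).

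Ribosomal protein and oxidative phosphorylation transcripts, which are short, rose as lists together with the excess of short transcripts. All 32 cytosolic ribosomal protein genes had a positive log2 fold change, with a mean of 0.77 (SE 0.534; camera adjusted p = 3.26e-10; adjusted p = 0.48 with an estimated correlation). The list mean of log2(FPKM + 1) was 7.32, 7.23, 6.19 and 5.18 in leukemic libraries 1 to 4 and 6.16, 5.69, 5.70 and 5.30 in control libraries 1 to 4. The oxidative phosphorylation list had 22 of 29 genes positive and a mean of 0.46 (SE 0.363; camera adjusted p = 0.0012; adjusted p = 0.485 with an estimated correlation). Neither list had a gene past the threshold adjusted over the list alone. With the length trend removed the means were 0.33 for ribosomal proteins and 0.07 for oxidative phosphorylation, whose call was lost (adjusted p = 0.513), and without leukemic libraries 1 and 2 they were -0.03 and -0.09. Without leukemic library 2 alone the oxidative phosphorylation call was lost (mean 0.24, adjusted p = 0.0752), and without leukemic library 4 its mean was 0.74. The ribosomal protein mean was 0.49 without leukemic library 1 and 1.203 without leukemic library 4.

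**Figure D3:**
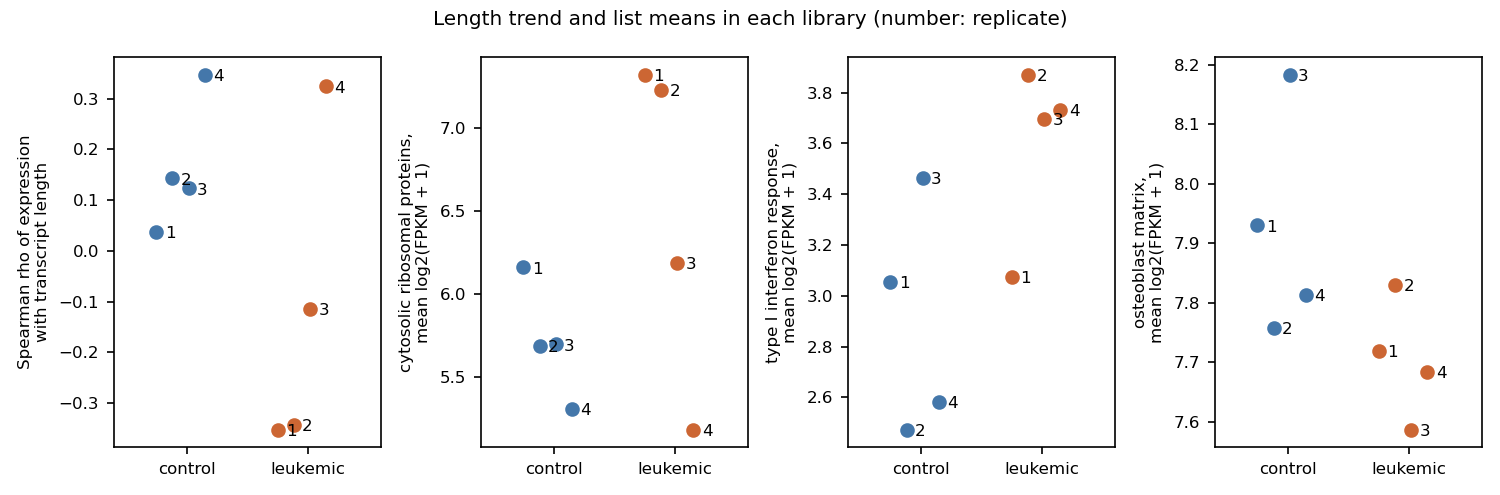
For each control (blue) and leukemic (orange) library, numbered by replicate, the Spearman rho of expression deviations with transcript length and the mean log2(FPKM + 1) of 3 gene lists. Leukemic libraries 1 and 2 have the lowest rho (-0.352 and -0.342) and the highest ribosomal protein means (7.32 and 7.23), while leukemic library 4 has the lowest ribosomal protein mean (5.18).

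Markers of other cell types that a sort of digested bone could hold were also measured. The Schwann and neural list rose by a mean of 0.47 (SE 0.169; camera adjusted p = 0.000506; adjusted p = 0.48 with an estimated correlation). Among the members that passed adjusted over the list alone were the myelin genes Mbp (32.0 ± 8.58 against 12.7 ± 6.00 FPKM) and Prx (2.44 ± 0.641 against 0.800 ± 0.512 FPKM), and 7 of 10 members were positive. The most abundant members, Pmp22 (284.5 ± 33.62 against 300.8 ± 103.7 FPKM) and S100b (47.41 ± 8.9 against 48.61 ± 7.347 FPKM), had slightly lower leukemic means. Cnp, the next in abundance, had a higher one (27.65 ± 6.856 against 20.88 ± 4.447 FPKM). Fibroblast and tendon markers rose by a mean of 0.45 with 16 of 18 positive (camera adjusted p = 0.00326; adjusted p = 0.485 with an estimated correlation), a call lost without control library 3 (mean 0.10, adjusted p = 0.569) and with a filter of 5 FPKM (adjusted p = 0.0635). The endothelial list rose by a mean of 0.48 over 5 genes (camera adjusted p = 0.0307; adjusted p = 0.48 with an estimated correlation), led by Ecscr (9.10 ± 3.03 against 2.57 ± 1.11 FPKM), the only member past the threshold adjusted over the list alone. Skeletal muscle (mean 0.36, camera adjusted p = 0.0116), Notch pathway (0.37, adjusted p = 0.0285) and pericyte (0.21, adjusted p = 0.0467) lists rose as well, each with an adjusted p = 0.48 with an estimated correlation. Leaving out single libraries ended the Notch and pericyte calls in 5 of 8 fits each, the endothelial and senescence calls in 4 each and the muscle call in 1. Without the low-value filter the endothelial mean was 0.08 (adjusted p = 0.678) and the Notch mean 0.18 (adjusted p = 0.202), and neither passed. With a filter of 5 FPKM the Notch (0.38, adjusted p = 0.0862) and pericyte (0.20, adjusted p = 0.198) calls were lost. The pericyte call was also lost with quantile normalization (0.18, adjusted p = 0.0568), array weights (0.16, adjusted p = 0.176), and length and GC trends removed (0.23, adjusted p = 0.0577). By camera on ranks the endothelial (adjusted p = 0.111) and pericyte (adjusted p = 0.0589) calls were lost. The muscle mean was -0.01 with the length trend removed (adjusted p = 0.781), and the endothelial, muscle, pericyte and fibroblast calls were lost without leukemic libraries 1 and 2. The means were then 0.26, 0.14, 0.20 and 0.30 (adjusted p = 0.189, 0.279, 0.154 and 0.066). Without leukemic library 2 the Notch mean was 0.24 (adjusted p = 0.108), and without control library 3 the pericyte mean was 0.07 (adjusted p = 0.355). The endothelial mean was 0.26 without control library 3 (adjusted p = 0.272) and 0.74 without leukemic library 4 (adjusted p = 0.0179). The macrophage (0.19, and -0.02 with the length trend removed), osteoclast (mean 0.12, median -0.06), pan-leukocyte (0.10), stromal (-0.07), chondrocyte (-0.08), erythroid (-0.20) and neutrophil (-0.28) lists did not pass. With the length trend removed, the neutrophil mean was -0.75 and passed camera with the preset correlation (adjusted p = 0.00424; adjusted p = 0.566 with an estimated correlation). It also passed without control library 4 (-0.62, adjusted p = 0.0214; adjusted p = 0.608 with an estimated correlation). The erythroid mean was -1.32 and passed without leukemic libraries 1 and 2 (adjusted p = 0.000803; adjusted p = 0.602 with an estimated correlation). The chondrocyte list passed in opposite directions without leukemic library 1 (-0.36, adjusted p = 0.0124) and without leukemic library 2 (0.24, adjusted p = 0.0151), with an adjusted p = 0.513 and 0.592 with an estimated correlation. The stromal list passed without control library 4 (-0.35, adjusted p = 0.0144; adjusted p = 0.648 with an estimated correlation). Of 24 B-lineage genes, 22 were in the table and 3 reached the level for testing, with a mean log2 fold change of 0.51 and 3 of 3 positive, too few for a list test. Without the filter the B-lineage list was tested over all 22, of which 17 were positive, and passed with the preset correlation (mean 0.27, adjusted p = 0.00265; adjusted p = 0.583 with an estimated correlation). Cd79a stood at 1.96 ± 1.46 FPKM (n = 4) in leukemic and 0.790 ± 0.599 FPKM (n = 4) in control libraries. The megakaryocyte list had 3 genes tested (mean -0.33) and the T and NK cell list 1 (0.14), so neither was tested as a list. Without the filter their means were -0.13 over 14 genes (adjusted p = 0.59) and 0.03 over 16 (adjusted p = 0.86). Mitochondrially encoded transcripts had 0 rows in the table used here.

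The remaining lists did not pass camera in the main fit. Lists with a negative mean were osteocyte (-0.26, adjusted p = 0.076), proliferation (-0.18, adjusted p = 0.0764) and Wnt ligands and receptors (-0.17, adjusted p = 0.166). Others were haematopoietic niche factors (-0.12, adjusted p = 0.509), mineralization (-0.11, adjusted p = 0.289), unfolded protein response (-0.07, adjusted p = 0.13), BMP and TGF-beta response (-0.05, adjusted p = 0.509) and p53 targets (-0.04, adjusted p = 0.611). With the length trend removed, the mineralization mean was -0.27 and passed with the preset correlation (adjusted p = 0.0207; adjusted p = 0.472 with an estimated correlation). The osteocyte list passed with a filter of 5 FPKM (-0.31, adjusted p = 0.0329), with quantile normalization (-0.31, adjusted p = 0.0367), without control library 1 (-0.29, adjusted p = 0.0443) and without control library 3 (-0.29, adjusted p = 0.0305). The proliferation list passed without leukemic library 1 (-0.28, adjusted p = 0.00192), control library 1 (-0.22, adjusted p = 0.0284) or control library 2 (-0.29, adjusted p = 0.00262), and without the filter (-0.19, adjusted p = 0.0443). The unfolded protein response list passed with quantile normalization (-0.18, adjusted p = 0.0123) and array weights (-0.11, adjusted p = 0.0426), and the Wnt ligand list with array weights (-0.23, adjusted p = 0.0496). In these fits the adjusted p of these 4 lists ran from 0.364 to 0.699 with an estimated correlation. Phex also passed adjusted over the list alone in the osteocyte and mineralization lists. Lists with a positive mean were osteoclast-regulating cytokines (0.25, adjusted p = 0.289) and matrix proteases (0.12, adjusted p = 0.604). So were glycolysis and hypoxia (0.05, adjusted p = 0.575) and the immediate early response to dissociation (0.03, adjusted p = 0.583). The glycolysis list passed without leukemic libraries 1 and 2 (0.23, adjusted p = 0.00108; adjusted p = 0.602 with an estimated correlation). Secreted Wnt antagonists had a mean of 0.00 and a median of -0.17 (adjusted p = 0.764).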

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

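Every test weighed here was chosen after the results were seen. A library far from the other 3 of its group was found in 11 of 162 groups of values examined, where chance gives about 8.1. Dkk1 was at 8.4 FPKM in leukemic library 2 and between 3.01 and 3.77 FPKM in the other leukemic libraries. Cybb was at 3.95 FPKM in leukemic library 1 and between 7.55 and 8.04 FPKM in the others. Slamf8 was at 0.15 FPKM and Sost at 0.13 FPKM in control library 1, with at most 0.02 and 0 FPKM in the other controls. Control library 3 stood apart for Sp7 (69.82 FPKM against 49.99 to 51.74), Cxcl9 (12.98 FPKM against 4.69 to 6.07), the mineralization list (mean log2 of 7.46 against 7.203 to 7.229) and the fibroblast and tendon list (5.296 against 6.639 to 6.719). The canonical Wnt target list was at 3.488 in leukemic library 1 and at 3.705 to 3.743 in the other leukemic libraries. The stress response list was at 6.239 in leukemic library 2 against 6.075 to 6.096, and the osteoclast list at 3.762 in control library 4 against 4.048 to 4.061.

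The first pattern weighed was the higher level of Ccl19, Cxcl13, Slamf8, C3 and Cybb in leukemic libraries. With the length trend removed, the median log2 fold change of the 5 genes was 2.13 (median SE 0.29), against 2.04 before. For the 5 genes as a set, this argues against the length trend as the cause. Only Ccl19 was highest in both leukemic libraries 1 and 2, which were richer in short transcripts. It stood at 156.31, 253.46, 83.8 and 31.18 FPKM in leukemic libraries 1 to 4. How much of the size of its difference follows length is not given here. Summed over Ccl19, Gm2564 and Gm12407, FPKM differed by 3.63 on the log2 scale (exact permutation p = 0.0286, the smallest 4 against 4 allows). Ccl19 was picked from these data for its small p and makes up most of the sum, so this p adds no support. A shift of reads from copies cannot be told apart for Ccl19, because 2 further copies were not analysed here. Gm2457, LOC100043921 and Gm13309 were not in the sum either. More leukocytes would raise all their abundant transcripts, but the median gain of 16 pan-leukocyte markers was 0.022 FPKM (SD 5.12, the highest being Arhgdib at 20.44, a gene already at 86.5 FPKM in controls) against a gain of 65.0 FPKM for C3 and 124.7 for Ccl19. Against more macrophages as the source of Cxcl13, Slamf8 and Cybb (a gain of 5.46 FPKM), 17 of 19 macrophage markers gained less than Slamf8 (2.99 FPKM), among them Cd68 (-1.79), Cd14 (-0.30), C1qa (-0.23), Adgre1 (-0.16) and Csf1r (0.05), and the list mean went from 0.194 to -0.021 with the length trend removed. Yet 2 markers gained more (Lyz2 by 39.91 and Vcam1, also in 3 other lists, by 34.97). Macrophages, which the sort would have to have let through, therefore cannot be told apart from a change within OBCs. Fibroblasts and other stromal cells as a source of the 5 genes were not tested. Chance stays open, since none of the 5 genes passed the threshold in the main limma fit. Ccl19, Cxcl13, C3 and Slamf8 passed only in some alternative fits.

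The second pattern was the higher level of ribosomal protein and oxidative phosphorylation transcripts. Against 10000 random lists matched on length and expression, the oxidative phosphorylation mean lay at percentile 88.36, which is consistent with the length trend as its source. The ribosomal protein mean lay at percentile 100 (upper limit of the random lists 0.564), yet it was -0.03 without leukemic libraries 1 and 2. Its genes vary together (estimated correlation 0.809), so random lists of unrelated genes understate its spread, and for this list a length effect cannot be told apart from a real difference. Why leukemic libraries 1 and 2 were richer in short transcripts was not tested.

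The third pattern was the lower level of osteoblast matrix transcripts. The mean of -0.22 lay at percentile 0.0 of the matched random lists, whose median was 0.07, and moved to -0.29 with the length trend removed, which argues against that trend as its cause. A lower share of OBCs in the leukemic sorts cannot be told apart from lower expression, because the fibroblast list was higher by 0.446 (SE 0.392), as a lower share would need, while the stromal list differed by -0.072 and the chondrocyte list by -0.079, within its SD of 0.225 between control libraries. Control library 3 had the highest osteoblast mean (8.183) and the lowest fibroblast mean (5.296). Without it the fibroblast difference was 0.099 and the osteoblast difference -0.129 (camera adjusted p = 0.199). Chance could not be excluded either: 3 of the 35 splits of the 8 libraries gave a mean difference as large, the real one being -0.216 and the highest of the others 0.252 in size. Lower expression in leukemic OBCs therefore stays a hypothesis.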

How the results depend on the processing

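The length and GC removals, the estimated correlation in each alternative fit and the fits without leukemic libraries 1 and 2 were chosen after seeing the data; the other alternatives were planned. No gene was lower in any alternative run. The number of higher genes was 0 with either pseudocount, a filter of 5 FPKM, median-ratio scaling, robust or untrended variances, the block, and without leukemic libraries 1 and 2 (258 higher and 385 lower unadjusted). It was 1 without the filter (Ntn5), 2 with totals rescaled to TPM (LOC100043921 and Ccl19; 171 higher and 725 lower unadjusted, since this moved the median log2 fold change to -0.15), 3 with quantile normalization (those and Cxcl13), 6 with array weights (those 3, Slamf8, C3 and Gm13309), 3 with the length trend removed (Ccl19, C3 and Gm2564), and 1 (Ccl19) with length and GC trends removed or with the length trend removed and the block. Leaving out single libraries gave 0 to 2 higher genes, the 2 without leukemic library 4 (1237 higher and 506 lower unadjusted), and the lowest adjusted p ran up to 0.724 without control library 2. Over all alternatives the adjusted p ran from 0.000249 to 0.724 for Ccl19 and from 0.026 to 0.833 for C3. The cause of these moves was not tested.

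The 15 lists past camera became 9 with a filter of 5 FPKM, where fewer genes were tested, 8 without leukemic libraries 1 and 2, and 0 with an estimated correlation or with fry; other settings gave 10 to 17, this range being that of leaving out single libraries. The type I interferon, inflammation, interferon gamma, ribosomal protein and Schwann lists (5 of the 15) passed without each library in turn. Without leukemic libraries 1 and 2, ribosomal proteins (-0.027) and oxidative phosphorylation (-0.086) reversed. Without single libraries the chondrocyte mean ran from -0.36 to 0.241, past the threshold at both ends. With the block the pericyte call was lost (0.214, adjusted p = 0.0744). With the length trend removed and the block, the erythroid list passed too (-0.567, adjusted p = 0.00439; adjusted p = 0.642 with an estimated correlation).

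Reversals among genes were in the bone panel, all with values that never passed. Bglap was -0.253 with array weights, -1.002 with the length trend removed, with or without the block, -1.004 with GC too, and -1.017 without leukemic libraries 1 and 2. Spp1 was 0.051 with array weights. Kitl was 0.030 with the length trend removed, with or without the block, 0.042 with GC too and 0.113 without leukemic libraries 1 and 2, where Alpl was 0.061, Col1a1 0.042 and Tnfrsf11b 0.026. Without single libraries the log2 fold change ran from -0.334 to 0.739 for Bglap, -0.305 to 0.323 for Spp1, -0.337 to 0.265 for Kitl, -0.604 to 0.131 for Cxcl12, -0.588 to 0.107 for Tnfsf11, -0.303 to 0.112 for Tnfrsf11b, -0.229 to 0.072 for Alpl, -0.769 to 0.069 for Dmp1 and -0.269 to 0.001 for Ibsp. The cause was not tested.

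The labels number samples 1 to 4 in both groups, and same-numbered samples had correlations of their deviations of 0.122, -0.047, -0.072 and 0.22. These values are few and of both signs, so they cannot decide whether the numbers pair the samples. With the replicate block 0 genes were higher and 0 lower (lowest adjusted p 0.0597) and 14 lists passed. At an unadjusted p under 0.05, limma then gave 633 higher and 405 lower genes, against 279 and 463 without the block. Leukemic libraries 1 and 4 correlated best with the control of their own number, and leukemic libraries 2 and 3 did not. Read depth is unknown, which leaves the precision of low genes such as Slamf8 open.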

Other observations

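The tests of splits here were chosen after the results were seen. Sorted OBCs of both groups held cartilage transcripts at the level of bone collagen. Chad, a cartilage matrix protein, stood at 10110 ± 2550 FPKM (n = 4) in leukemic and 9021 ± 3271 FPKM (n = 4) in control libraries, and Col2a1, the main collagen of cartilage, at 6293 ± 3777 against 6354 ± 1061 FPKM, beside 6275 ± 2972 and 7880 ± 1051 FPKM for Col1a1. Sost was at 0.16 FPKM or less in all 8 libraries. Other genes of the marker lists, chosen after their values were seen, were Hp, the acute phase gene haptoglobin (914 ± 243 against 368 ± 223 FPKM, limma adjusted p = 0.6393, higher in 4 of 4), Mmp9, a gelatinase (59.6 ± 31.2 against 19.4 ± 17.2 FPKM, adjusted p = 0.6393), and Lyz2, lysozyme (82.9 ± 34.0 against 43.0 ± 5.57 FPKM, adjusted p = 0.695). Most genes tested of the stromal and neutrophil lists went the other way, but those of the macrophage list mostly did not. Log2 fold changes were negative in 14 of 21 genes tested of the stromal list, which holds Hp. They were negative in 8 of 11 of the neutrophil list, which holds Mmp9, and in 3 of 8 of the macrophage list, which holds Lyz2. Vpreb1, a pre-B-cell receptor component, was at 2.21 ± 1.83 FPKM in leukemic and 0.292 ± 0.219 FPKM in control libraries and was not tested.

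The 8 libraries can be split into 2 groups of 4 in 35 ways. The real counts of 0 higher and 0 lower genes are reached by all 35 splits whatever the data, so this comparison says nothing about chance. The highest of the others gave 573 genes in 1 direction. That split set leukemic libraries 1, 2 and 3 and control library 1, the 4 with the most short-transcript signal, against the rest, which points to transcript length as a structure of these samples. At an unadjusted p under 0.05, 9 splits gave as many genes as the real 742, with up to 1533 in the others, so chance could not be excluded. For lists past camera, 2 splits gave as many as the real 15 (highest other 16), so chance could not be excluded for their number. With the length trend removed, 2 splits gave as many genes as the real 3 (highest other 3), so chance could not be excluded there.

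Of single lists, the type I interferon mean of 0.70 was reached in 2 of the 35 splits, the real one included (highest other 0.895), so chance could not be excluded. For the canonical Wnt targets the real split gave the largest difference in size, -0.255 against 0.244 in the others, which is 1 of 35 splits. That share is the smallest the design allows. It was the 1 list of 35 with the real split on top, and about that many are expected from 35 lists, so chance stays open for a list picked from them. Lower Wnt target expression in leukemic OBCs is consistent with this value and remains a hypothesis, as the call was lost with the length trend removed (mean -0.195, adjusted p = 0.067), under the other settings given with it, and with an estimated correlation (adjusted p = 0.48).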
